A study of Mus musculus with 12 samples.

How the data were processed

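The study compares wild-type and Orai1-knockout mouse CD4 T cells grown for 48 h towards non-pathogenic Th17 (npTh17) or pathogenic Th17 (pTh17) cells. Naive cells from spleen and lymph nodes of female mice aged 8 to 12 weeks were stimulated through CD3 and CD28, and the deletion was made with a CD4-Cre transgene. By the sample labels, npTh17 cultures received IL-6 (30 ng/ml) with TGF-β (1 ng/ml), and pTh17 cultures received IL-6 (30 ng/ml), IL-23 (10 ng/ml) and IL-1β (10 ng/ml). Both had antibodies against IL-4 and IFN-γ (the latter at 10 µg/ml). Bulk RNA was made into stranded libraries after ribosomal RNA was removed with RNase H, and single-end reads of 50 nucleotides were taken. There are 12 libraries, 3 in each of 4 groups.

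The labels state that cells of 3 mice per genotype were pooled once harvested, and that each condition has 3 technical replicates made from the pool, while the library names number the controls and knockouts 1 to 3. Taken as labelled, p-values measure only the spread between libraries from the same pool and not the spread between mice. Group and number were taken from the library names, because some titles name pTh1 or npTh1 where the library name and the treatment field name pTh17 or npTh17. Which part of Orai1 is deleted and whether the controls carry Cre are not given in the sources used here.

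The submitters used bcl2fastq 2.19.1.403 and STAR 2.7.8a, followed by Partek, whose version is not given in the sources used here. Both GRCm39 and mm10 are named without their role, and the tables do not name a genome build, so positions below are those of the tables. The deposited tables are a count table, in which 20.2% of values are not whole numbers, so that its unit was taken to be the estimated count, and a CPM table, in which counts are scaled to a common library total. The CPM table equals count over library total plus 0.0001, with a largest relative difference of 0.388%. The count table was used, rounded to whole numbers for edgeR and DESeq2. All per-gene CPM values here are scaled by trimmed mean of M-values (TMM) factors.

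Choices of groups, comparisons, tests, thresholds, gene lists and alternative settings were fixed before the data were examined, apart from those named below as added later. Of 55357 genes, 15238 passed filterByExpr. The test was the quasi-likelihood F test of edgeR 4.0.16 on all 12 libraries with TMM factors, run in R 4.3.3. It had 5 comparisons: knockout against wild type in each culture, pTh17 against npTh17 in each genotype, and the interaction. A gene passed at an adjusted p (Benjamini-Hochberg, over all tested genes) under 0.05, and a further count asks for a change of at least 2-fold. SE is the log2 fold change over the square root of F. Alternatives used limma 3.58.1 and DESeq2 1.42.0. Rows without a gene name (1362) were kept.

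The 34 gene lists cover Th17 biology, signalling, metabolism, stress, other cell types and RNA quality, and were tested with camera on voom values (preset correlation 0.01) when at least 3 members were measured. The test was repeated with the correlation estimated from the data and with fry. Genes named in the text follow a rule fixed at the same time as the lists. It takes the Orai and Stim genes and a short set of T cell genes, among them Il17a, Il17f, Il22, Csf2 and Il2, always. From each list described it takes up to 4 members that passed with the largest changes and at least 5 CPM in the higher group. It adds the 6 largest rises and 6 largest falls among genes that passed with separate library ranges and at least 10 CPM. For wild-type pTh17 against npTh17 it was applied to the blocked fit described below. In knockout pTh17 against npTh17 the rule gives only the genes always taken and genes named in another comparison. Other genes are marked as chosen after the values were seen.

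The libraries of one genotype that share a number tended to be alike across the cultures, more clearly in knockout than in wild type. Correlations of their deviations from the group mean were 0.46, 0.22 and 0.03 in wild type and 0.40, 0.50 and 0.28 in knockout, where more than 0.1 in every pair had been asked for. In wild type, npTh17 library 3 was closer to pTh17 library 2 (0.14) than to pTh17 library 3 (0.03). Wild-type and knockout libraries with the same number went together less regularly (0.19, 0.44 and −0.04 in npTh17, and −0.15, 0.05 and 0.07 in pTh17). Genes that are on in 1 library and off in another of its group followed the number within a genotype in both cultures. A fit with the replicate as a block within genotype is therefore given beside the pTh17 against npTh17 results. This choice was made after both counts were seen, and wild-type pair 3 misses the criterion, so the count without the block comes first. The common biological coefficient of variation was 0.158 without and 0.112 with that block. With genotype and number as a random block in limma (consensus correlation 0.263), no wild-type gene passed.

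The pipeline was tested on simulated counts with 200 changed genes of 15238. In knockout against wild type it recovered 22.4% (npTh17) and 20.9% (pTh17) of genes changed 1.5-fold, 56.7% and 71.6% at 2-fold, and 93.9% and 78.8% at 4-fold. Calls on unchanged genes were 8 of 123 and 5 of 122. For pTh17 against npTh17 at 1.5-fold the block raised recovery from 23.9% to 46.3% in wild type and from 19.4% to 44.8% in knockout. Calls on unchanged genes rose with the block too, from 1 of 123 to 15 of 160 in wild type. In knockout they rose from 1 of 111 to 17 of 157. In these simulated counts the block therefore gained recovery at the cost of a larger share of false calls. For the interaction, recovery without the block was 2.99%, 46.3% and 78.8% at the 3 sizes.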

Results

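Library totals were 24, 23.2 and 33.3 M estimated counts for wild-type npTh17 libraries 1 to 3, and 25.1, 20.2 and 23.9 M for wild-type pTh17. The knockout libraries had 26.4, 23.9 and 22.3 M (npTh17) and 21, 33.7 and 24.8 M (pTh17). The ribosomal RNA gene Rn18s-rs5 took 4.49% to 8.71% of the counts and mitochondrial genes took 3.26% to 3.76%. TMM factors lay between 0.968 and 1.03.

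Orai1 encodes the pore of the calcium channel that opens in the plasma membrane when the endoplasmic reticulum store is emptied, and it is the gene deleted here (chromosome 5, 123153137 to 123168519, plus strand). Wild-type libraries held 21.4, 33.9 and 27.1 CPM in npTh17 and 25, 25.4 and 24.8 CPM in pTh17. Knockout libraries held 0.257, 0.334 and 0.436 CPM in npTh17 and 0.788, 0.424 and 0.902 CPM in pTh17. Orai1 fell 79.9-fold in npTh17 (log2 fold change −6.32, SE 0.27, adjusted p = 6.36e-07, edgeR) and 36.5-fold in pTh17 (−5.19, SE 0.25, adjusted p = 1.98e-06). None of its relatives passed the test in either culture. Orai2, whose product joins the same channels, was at 0.31 (adjusted p = 0.355) and 0.39 (0.277), and Orai3 was at −0.47 (0.540) and −0.28 (0.817). Stim1 and Stim2, which encode the store sensors, were at −0.13 (0.574) and −0.03 (0.943) in npTh17 and at −0.01 (0.985) and −0.03 (0.960) in pTh17.

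In npTh17 cultures, Orai1-knockout cells held far less mRNA of several Th17 and T cell cytokines than wild-type cells. Il17a, the signature cytokine of Th17 cells, fell 14.3-fold, from 61.9 ± 20.6 to 4.28 ± 1.73 CPM (mean ± SD, n = 3 libraries per group throughout), and Il17f, its close relative, fell from 617 ± 162 to 148 ± 58.2 CPM. Il2, the T cell growth factor, fell 5.41-fold, from 39.2 ± 11.5 to 7.23 ± 2.35 CPM. Mxd1, which encodes an antagonist of MYC, rose from 34.8 ± 1.94 to 77.7 ± 6.78 CPM, and Lrrc32, which encodes the docking receptor of latent TGF-β on regulatory T cells, rose from 14.8 ± 3.20 to 29.1 ± 4.55 CPM. Of 15238 genes, 121 passed (44 higher and 77 lower in the knockout), and 55 of these changed at least 2-fold (21 higher, 34 lower).

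**Figure D1:**
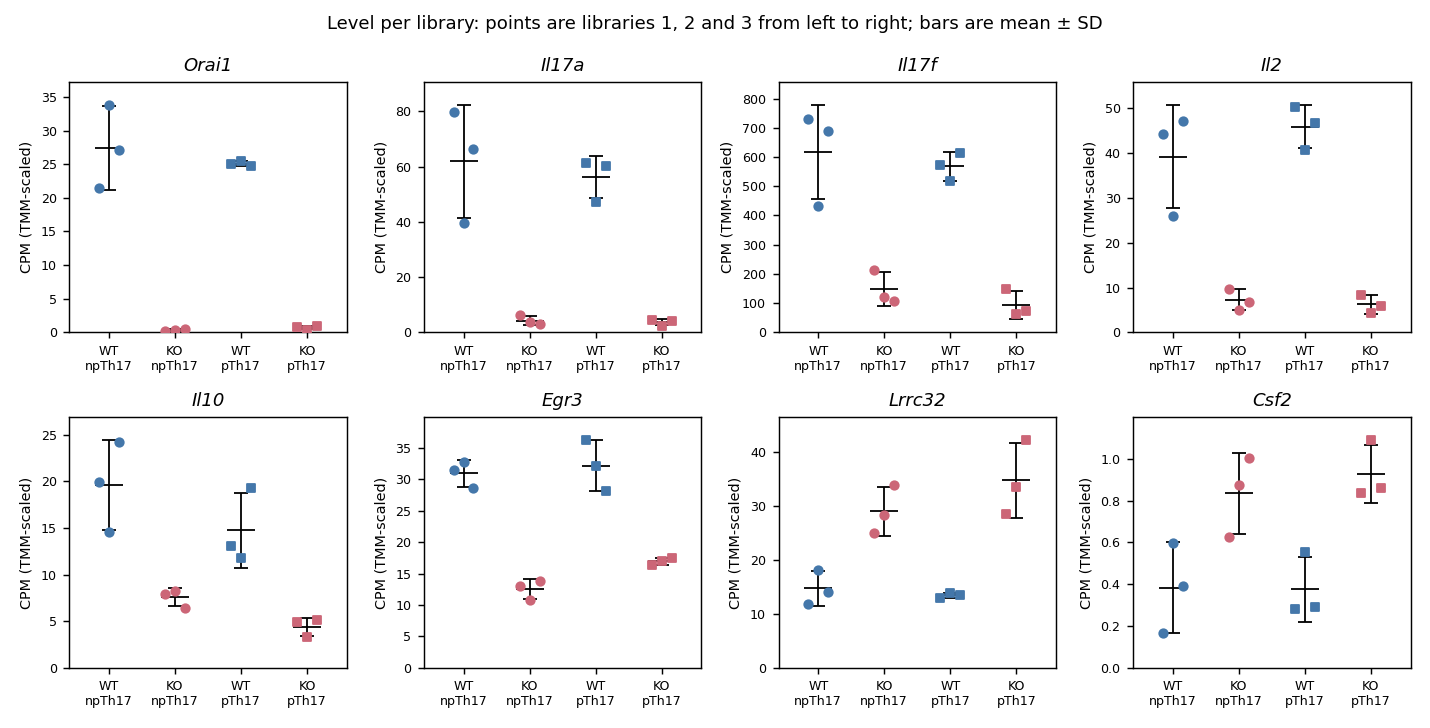
Level of 8 genes in each library (TMM-scaled CPM, axis from 0) for wild-type and knockout npTh17 and pTh17 cultures; points are libraries 1 to 3 from left to right and bars are mean ± SD. Il17a, Il17f, Il2 and Egr3 are lower and Lrrc32 is higher in the knockout in both cultures.

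Targets of calcineurin and NFAT, the pathway that store-operated calcium entry switches on in T cells, were the list with the smallest p in npTh17. Of 20 measured members, 7 fell and 13 did not pass, with a median of −0.78 (camera adjusted p = 1.99e-12; 0.0182 with an estimated correlation). Adjusted over the list alone, 14 fell and 2 rose. Beside Il2 (−2.43, SE 0.29, adjusted p = 0.00269), the members above 5 CPM with the largest falls were Cd40lg (−1.43, SE 0.16, 0.00200), the help signal to B cells and antigen-presenting cells, and Egr3 (−1.30, SE 0.12, 5.08e-04), an early transcription factor after T cell receptor signalling. Nfatc1 (−0.86, SE 0.11, 0.00556), an NFAT gene that NFAT itself induces, went from 115 ± 7.39 to 63.5 ± 6.86 CPM. Among 20 cytokine genes 4 fell, which were Il17a (−3.84, SE 0.34, 4.46e-04), Il17f (−2.06, SE 0.35, 0.0196), Il2 and Il10 (−1.37, SE 0.23, 0.0206), the last an anti-inflammatory cytokine. This list had a median of −0.76 and camera adjusted p = 2.46e-06 (0.0279 with an estimated correlation), and adjusted over the list alone 11 fell and 2 rose. Csf2, which encodes the cytokine GM-CSF, was at 0.835 and 0.385 CPM in knockout and wild type (1.1, SE 0.41, adjusted p = 0.309). Il22, which acts on epithelia, was near the counting floor in both (0.0507 and 0.303 CPM; −2.48, SE 1.01, 0.366).

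In the Th17 lineage list 3 of 20 genes fell in npTh17, Il17a, Il17f and Batf (−0.47, SE 0.09, adjusted p = 0.0421), a factor needed for Th17 differentiation. Adjusted over the list alone 6 fell (camera adjusted p = 1.40e-06; adjusted p = 0.138 with an estimated correlation). From the published non-pathogenic signature 2 of 8 genes fell (4 adjusted over the list alone), Il10 and Cd5l (−2.08, SE 0.32, 0.0112), a regulator of lipid synthesis that restrains pathogenicity (camera adjusted p = 0.0133; adjusted p = 0.470 with an estimated correlation). From the pathogenic signature 3 of 14 fell. They were Lag3 (−2.09, SE 0.36, 0.0206), an inhibitory receptor that is also an activation marker, and the chemokine genes Ccl4 (−3.84, SE 0.36, 5.18e-04) and Ccl3 (−2.52, SE 0.48, 0.0342). Both chemokines were chosen after the values were seen, as they lie below 5 CPM. Adjusted over the list alone 3 fell and 1 rose, and the list did not pass camera (0.0714). Ccl3 and Ccl4 were also the only 2 of 24 chemokine and trafficking genes to fall, 2 adjusted over the list alone (camera adjusted p = 0.0161; adjusted p = 0.122 with an estimated correlation).

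Regulatory T cell genes held 3 of 12 members that rose in npTh17, namely Gpr83 (1.07, SE 0.18, adjusted p = 0.0185), a receptor found on these cells, Lrrc32 (0.98, SE 0.18, 0.0267) and Izumo1r (0.81, SE 0.12, 0.0112), the folate receptor FR4. Adjusted over the list alone 4 rose and 1 fell. The list did not pass camera (adjusted p = 0.0874, and 0.256 with an estimated correlation) but passed fry (adjusted p = 0.00131). Irgm1 (0.81, SE 0.16, 0.0421), an interferon-induced GTPase, rose alone among 14 interferon-stimulated genes, 4 adjusted over the list alone (camera adjusted p = 0.0219; adjusted p = 0.274 with an estimated correlation). Nfkbia (−0.68, SE 0.12, 0.0281), the NF-κB inhibitor, fell alone among 14 genes of IL-1 and NF-κB response, 4 adjusted over the list alone (camera adjusted p = 0.00515; adjusted p = 0.205 with an estimated correlation). Itpr1 (−0.69, SE 0.13, 0.0406), the calcium release channel of the store, and Orai1 fell among 24 genes of the calcium entry machinery, 2 adjusted over the list alone (camera adjusted p = 0.100). Btg2 (0.55, SE 0.09, 0.0135), which keeps T cells quiescent, rose among 17 naive and quiescence genes, 2 adjusted over the list alone, where the median was −0.04 and the mean 0.06 (camera adjusted p = 0.380). Activation markers had a median of −0.13 over 15 genes, with Lag3 lower (camera adjusted p = 0.0869; adjusted over the list alone 2 fell and 1 rose).

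Among genes with at least 10 CPM in the higher group and separate library ranges, the largest rises in npTh17 were Dab2 (2.04, SE 0.33, adjusted p = 0.0164), an adaptor of endocytosis present in regulatory T cells, Myo6 (2.03, SE 0.30, 0.00928), a motor of endocytic vesicles, and Gja5 (1.53, SE 0.28, 0.0310), a connexin of gap junctions. Next came Anxa3 (1.51, SE 0.27, 0.0267), a calcium-dependent phospholipid-binding protein, Ctla2a (1.24, SE 0.19, 0.0122), a cathepsin inhibitor at 296 ± 42.6 against 125 ± 19.4 CPM, and Mxd1 (1.16, SE 0.13, 0.00200). The largest falls under the same limits, beside those above, were Tspan2 (−2.54, SE 0.30, 0.00248), a membrane tetraspanin, and Zbtb32 (−2.08, SE 0.23, 0.00200), a transcription factor that restrains T cell proliferation. Lists of metabolism, stress and RNA quality passed camera without a member past the test over all genes. Oxidative phosphorylation genes (75, median 0.08, camera adjusted p = 0.00137; adjusted p = 0.649 with an estimated correlation) and ATF4 targets (19 genes, camera adjusted p = 0.00841; adjusted p = 0.371 with an estimated correlation) were higher. Amino acid and one-carbon genes (18, camera adjusted p = 0.00841; adjusted p = 0.444 with an estimated correlation) and structural RNAs (5, median −0.69, camera adjusted p = 0.00197; adjusted p = 0.168 with an estimated correlation) were lower. Genes of p53 and apoptosis (18, camera adjusted p = 0.0133; adjusted p = 0.122 with an estimated correlation) were higher. In these lists 3 ATF4 targets and 1 p53 gene rose and 2 structural RNAs fell when adjusted over the list alone. In all, 12 lists passed camera in npTh17, and with an estimated correlation 2 did, the NFAT targets and the cytokines.

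Markers of other cell types differed between libraries. The mean log2 CPM of B cell markers was −0.02, 0.24 and −0.34 in wild-type npTh17 libraries 1 to 3 and −0.71, 1.47 and 0.87 in knockout ones. In pTh17 it was 0.18, 0.36 and −0.13 in wild type and −0.48, 1.73 and 1.41 in knockout. Antigen-presenting and myeloid markers were at 0.78, 2.82 and 2.18 in knockout npTh17 libraries against 0.78, 1.28 and 1.11 in wild type. As lists, B cell markers (median 0.91 in npTh17, 1.28 in pTh17) had camera adjusted p = 0.261 and 0.0323 (adjusted p = 0.652 with an estimated correlation for the latter). Myeloid markers (median 1.02 and 1.06) had camera adjusted p = 0.0548 and 0.0142 (adjusted p = 0.543 with an estimated correlation for the latter). CD8 T and NK cell markers (median 1.06 in npTh17 and 0.69 in pTh17) had camera adjusted p = 0.0752 and 0.460.

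The number of npTh17 genes past the test fell when a library was left out. It was 60, 58 and 52 without wild-type npTh17 library 1, 2 or 3, and 40 and 35 without knockout npTh17 library 1 or 3. Such fits keep only 2 libraries in a group and apply the gene filter anew. Lost power and the weight of a single library are therefore not told apart. DESeq2 on all libraries gave 393. Of 26 named genes that passed, 9 stayed past the test whichever of the 12 libraries was left out (Orai1, Il17a, Il2, Cd40lg, Egr3, Nfatc1, Mxd1, Tspan2 and Zbtb32). The other 17 were lost without at least 1 library, with highest adjusted p from 0.0513 (Myo6) to 0.222 (Batf), and Il17f was lost without wild-type npTh17 library 1 or 3 or knockout npTh17 library 2 or 3 (up to 0.137).

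In pTh17 cultures the same cytokines stood out. Il17a fell 15.6-fold in the knockout, from 56.2 ± 7.71 to 3.67 ± 1.16 CPM (log2 fold change −3.96, SE 0.34, adjusted p = 5.06e-04, edgeR). Il17f fell 5.99-fold, from 568 ± 49.2 to 95.0 ± 47.8 CPM (−2.58, SE 0.35, 0.00802), and Il2 fell 7.43-fold, from 46.0 ± 4.89 to 6.26 ± 2.05 CPM (−2.89, SE 0.30, 0.00195). Lrrc32 rose from 13.5 ± 0.468 to 34.8 ± 6.91 CPM (1.37, SE 0.18, 0.00675). Of 15238 genes, 72 passed (28 higher, 44 lower) and 41 changed at least 2-fold (12 higher, 29 lower).

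Among 20 Th17 lineage genes in pTh17, Il17a and Il17f fell and 18 did not pass (7 fell adjusted over the list alone), with a median of −0.50 (camera adjusted p = 1.65e-12; 0.0285 with an estimated correlation). Of 20 NFAT targets 6 fell, 12 adjusted over the list alone with 2 that rose (median −0.58, camera adjusted p = 2.55e-11; 0.0185 with an estimated correlation). Named members were Il2, Cd40lg (−1.06, SE 0.16, 0.0119), Egr3 (−0.92, SE 0.12, 0.00658; 16.9 ± 0.527 against 32.1 ± 4.08 CPM) and Nfatc1 (−0.65, SE 0.11, 0.0334). Of 20 cytokine genes 4 fell, Il10 among them (−1.75, SE 0.24, 0.00832), and 10 fell and 2 rose adjusted over the list alone (median −0.82, camera adjusted p = 6.70e-07; 0.0185 with an estimated correlation). Of 24 chemokine and trafficking genes 2 fell (3 adjusted over the list alone; camera adjusted p = 6.84e-04; 0.0285 with an estimated correlation), Ccl4 (−4.28, SE 0.36, 5.06e-04) and Ccl3 (−3.53, SE 0.49, 0.00832), both chosen after the values were seen. Csf2 was at 0.929 against 0.375 CPM (1.33, SE 0.41, 0.272) and Il22 at 1.27 ± 0.605 against 3.06 ± 1.42 CPM (−1.26, SE 0.53, 0.484), neither past the test.

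Regulatory T cell genes in pTh17 gave 3 rises among 12 members (4 rose and 1 fell adjusted over the list alone), Lrrc32, Gpr83 (1.19, SE 0.18, adjusted p = 0.0126) and Izumo1r (0.96, SE 0.12, 0.00675). The median was 0.22 and the list passed (camera adjusted p = 9.35e-04; 0.0285 with an estimated correlation). Both Th17 signatures were lower. In the pathogenic one Lag3 (−2.11, SE 0.35, 0.0263), Ccl3 and Ccl4 fell among 14 genes (4 fell and 2 rose adjusted over the list alone; camera adjusted p = 9.35e-04; adjusted p = 0.128 with an estimated correlation). In the non-pathogenic one Il10 and Cd5l (−1.87, SE 0.31, 0.0253) fell among 8 genes (4 adjusted over the list alone; camera adjusted p = 1.04e-04; adjusted p = 0.341 with an estimated correlation). Activation markers had a median of −0.17 (15 genes, Lag3 lower, camera adjusted p = 0.0622). Cholesterol synthesis genes (24) had camera adjusted p = 0.00668 and mitochondrially encoded genes (15) had 0.00816, both higher (adjusted p = 0.550 and 0.543 with an estimated correlation). ATF4 targets (camera adjusted p = 0.0119; adjusted p = 0.543 with an estimated correlation) and p53 genes (camera adjusted p = 0.0280; adjusted p = 0.128 with an estimated correlation) were higher too. With at least 10 CPM in the higher group and separate library ranges, the largest other rises were Gvin1 (2.12, SE 0.37, 0.0334), an interferon-induced GTPase at 39.9 ± 19.9 against 9.17 ± 2.55 CPM, Mxd1 (1.18, SE 0.13, 0.00207) and Enah (0.99, SE 0.13, 0.00802), a regulator of actin filaments. Tspan2 had the largest further fall under these limits (−2.69, SE 0.31, 0.00321). In all, 13 lists passed camera in pTh17, and with an estimated correlation 5 did: Th17 lineage genes, NFAT targets, cytokines, chemokines and regulatory T cell genes.

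The pTh17 count was 32, 32 and 36 without wild-type pTh17 library 1, 2 or 3, 37 and 28 without knockout pTh17 library 1 or 3, and 42 without knockout npTh17 library 1. A fit on the 6 pTh17 libraries alone gave 8 and DESeq2 gave 269. Of 17 named genes that passed, 10 stayed past the test whichever library was left out (Orai1, Il17a, Il2, Il10, Egr3, Lrrc32, Izumo1r, Mxd1, Enah and Tspan2), and Il17f was lost without knockout pTh17 library 3 (adjusted p = 0.0568).

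**Figure D2:**
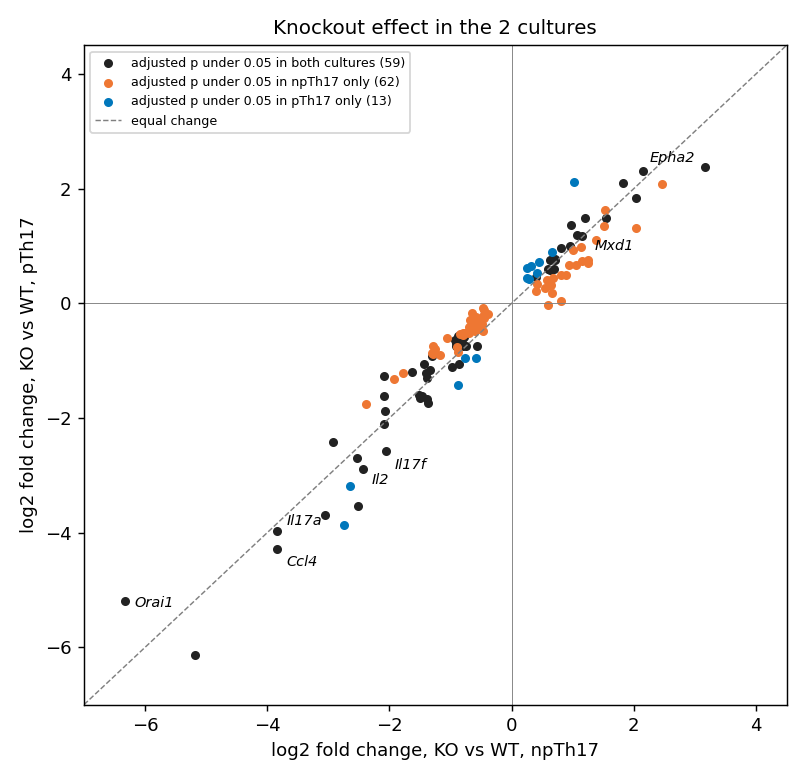
Log2 fold change of knockout against wild type in npTh17 (horizontal) and pTh17 (vertical) for the 134 genes that passed in either culture. Colour shows whether a gene passed in both cultures, npTh17 only or pTh17 only, and the dashed line marks equal change. Some larger rises lie beyond the axes, Gh and Gm38326 among them. The genes shown were selected for passing, and those past the test in both cultures lie near the line.

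Of the genes that changed with the knockout, 20 rose in both cultures and 39 fell in both, and 0 changed in opposite directions. The comparisons are not independent, as libraries of 1 genotype and number are alike across the cultures. The shared genes include Il17a, Il17f, Il2, Il10, Egr3, Nfatc1, Cd40lg, Lag3, Tspan2, Mxd1, Lrrc32, Gpr83 and Izumo1r. Over all 15238 genes the knockout effects in the cultures correlated at 0.512. On log2 CPM the value was 0.488, and other ways to divide the 6 numbered pairs of libraries into 2 genotypes gave 0.179 to 0.574, so this correlation is no larger than mixed labels can give.

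Between wild-type pTh17 and npTh17 cells, Il22, a cytokine made after IL-23 signalling, differed most among the named genes, at 3.06 ± 1.42 against 0.303 ± 0.238 CPM (n = 3). Il17a was at 56.2 ± 7.71 against 61.9 ± 20.6 CPM and Il17f at 568 ± 49.2 against 617 ± 162 CPM, close to equal. Foxp3, a TGF-β-induced regulatory factor, was at 23 ± 15.5 against 50.1 ± 15 CPM, where only npTh17 cultures had received TGF-β. Without pairing, edgeR passed 0 of 15238 genes (830 at unadjusted p < 0.05, smallest adjusted p = 0.140), limma voom also passed 0 and DESeq2 passed 16. With libraries of the same genotype and number taken as pairs, edgeR passed 89 (22 higher and 67 lower in pTh17; 1504 at unadjusted p < 0.05), of which 28 changed at least 2-fold (7 higher, 21 lower).

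With the pairs, Il22 rose 9.80-fold (3.29, SE 0.34, adjusted p = 0.0152; without pairs 3.23, SE 0.61, 0.425). The pathogenic Th17 signature held 3 genes of 14 that rose, Il22, Icos (1.03, SE 0.16, 0.0382), a costimulatory receptor at 244 ± 49.9 against 119 ± 25.4 CPM, and Stat4 (0.91, SE 0.14, 0.0382), which carries IL-12 and IL-23 signals. Adjusted over the list alone 6 rose. Camera gave adjusted p = 4.01e-09 with and 1.69e-06 without pairs (adjusted p = 0.0594 and 0.162 with an estimated correlation). The non-pathogenic signature held 3 of 8 genes that fell, Maf (−0.81, SE 0.10, 0.0168), a driver of Il10, Il1rn (−0.82, SE 0.12, 0.0327), the IL-1 receptor antagonist, and Il9 (−0.59, SE 0.09, 0.0330), a cytokine induced by TGF-β. Adjusted over the list alone 6 fell (camera adjusted p = 8.63e-09 with and 1.39e-04 without pairs; adjusted p = 0.0594 and 0.465 with an estimated correlation). Of 15 TGF-β response genes 5 fell, 10 adjusted over the list alone with 1 that rose (median −0.32; camera adjusted p = 3.99e-10 with and 1.69e-06 without pairs; adjusted p = 0.0594 and 0.419 with an estimated correlation). They include Foxp3 (−1.26, SE 0.18, 0.0282), Id1 (−0.79, SE 0.10, 0.0222), a target of SMAD signalling, Ldlrad4 (−0.71, SE 0.10, 0.0282) and Pmepa1 (−0.50, SE 0.08, 0.0381), both feedback inhibitors of the TGF-β pathway.

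Of 11 Th1 genes, Il12rb2 (1.59, SE 0.20, adjusted p = 0.0196), a chain of the IL-12 receptor, and Stat4 rose with pairs, 3 adjusted over the list alone (camera adjusted p = 0.00187 with and 0.00946 without pairs; adjusted p = 0.153 and 0.419 with an estimated correlation). In the Th17 lineage list Il22 rose and Ccl20 (−1.09, SE 0.17, 0.0356), the ligand of CCR6, and Maf fell, 2 higher and 7 lower adjusted over the list alone. Its median was −0.16 and its mean 0.05 (camera adjusted p = 0.00320 with pairs, lower, and 0.105 without; adjusted p = 0.338 and 0.756 with an estimated correlation). With pairs all 22 glycolysis genes were on the higher side, with a median of 0.14 (camera adjusted p = 6.38e-08 with and 0.0698 without pairs). These genes moved together, with an estimated correlation of 0.34 with and 0.82 without pairs. Camera with that correlation gave adjusted p = 0.338 and 0.872. Igfbp4, a binding protein of insulin-like growth factors at 330 ± 30.1 against 462 ± 20.8 CPM, fell (−0.49, SE 0.08, 0.0379). At 10 CPM or more in the higher group and with separate library ranges, the other large rises with pairs were Tnip3 (1.54, SE 0.11, 0.00712), an inhibitor of NF-κB, Plxnc1 (1.23, SE 0.18, 0.0288), a semaphorin receptor, Sik1 (0.58, SE 0.09, 0.0426), a kinase that acts on CREB coactivators, and Dennd5a (0.56, SE 0.07, 0.0168), a regulator of membrane transport. The large falls within these limits were Stab1 (−1.24, SE 0.14, 0.0152), a scavenger receptor, Aqp3 (−1.13, SE 0.12, 0.0152), a water and glycerol channel, Angptl2 (−1.11, SE 0.13, 0.0168), a secreted angiopoietin-like protein, and Acsbg1 (−1.08, SE 0.12, 0.0152), an acyl-CoA synthetase. Crispld2 (−1.0, SE 0.09, 0.0135), a secreted protein that binds lipopolysaccharide, and Spsb1 (−0.97, SE 0.14, 0.0282), an adaptor of a ubiquitin ligase, fell as well.

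With pairs, Il17a (−0.09, SE 0.17, adjusted p = 0.907), Il17f (−0.09, SE 0.13, 0.874), Il2 (0.27, SE 0.12, 0.514), Csf2 (−0.02, SE 0.37, 0.993) and Orai1 (−0.11, SE 0.13, 0.851) did not pass in wild type. Nor did Orai2 (−0.16, 0.662), Orai3 (0.16, 0.773), Stim1 (−0.12, 0.703) or Stim2 (−0.01, 0.981). The paired count of 89 fell to 0 without wild-type pair 1 (1010 at unadjusted p < 0.05, smallest adjusted p = 0.0548), 1 without pair 3, 30 without knockout pair 2 and 48 without knockout pair 1, so none of the 24 named genes that passed stayed past the test in every case, while none turned in sign. Without pairs 4 lists passed camera (12 without wild-type npTh17 library 2, 7 without wild-type pTh17 library 1) and with pairs 9 did, none of them with an estimated correlation.

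**Figure D3:**
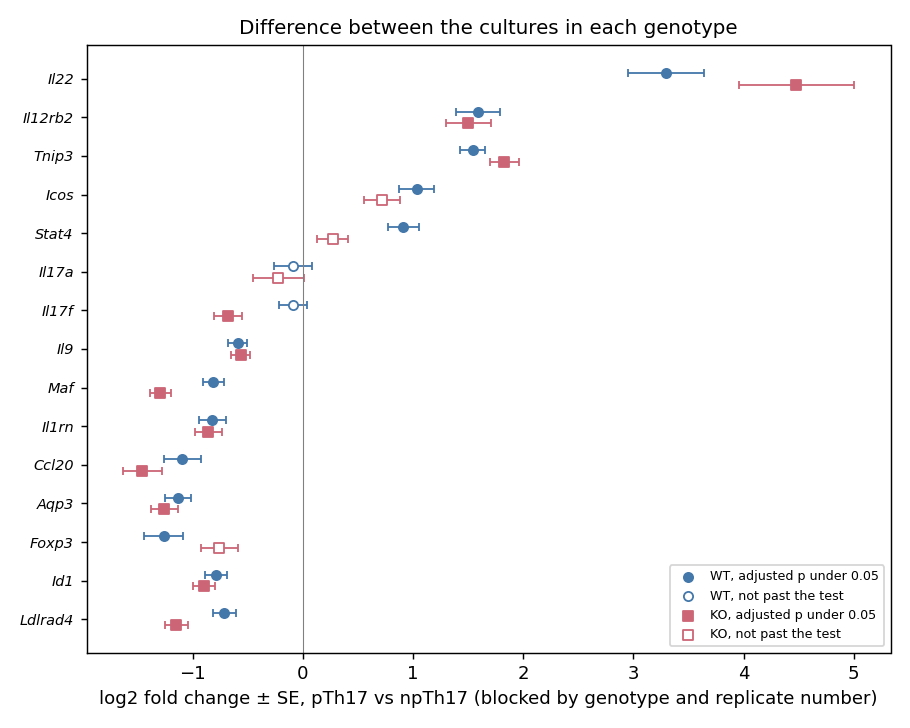
Log2 fold change ± SE of pTh17 against npTh17 for 15 genes in wild type (circles) and knockout (squares), from the fit with libraries paired by genotype and number; filled symbols have adjusted p < 0.05. Il22 is the largest rise in both genotypes, and Maf and Ccl20 are lower in both.

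In knockout cells, pTh17 cultures also had more Il22 than npTh17 cultures, at 1.27 ± 0.605 against 0.0507 ± 0.0557 CPM, with the npTh17 level near the counting floor. Maf was at 118 ± 33.3 against 287 ± 63.2 CPM and Ccl20 at 9.08 ± 5.48 against 23 ± 9.12 CPM (n = 3). Without pairs edgeR passed 2 genes, both lower in pTh17: Lbp (−1.37, SE 0.17, adjusted p = 0.0406; 13 ± 2.60 against 33.4 ± 2.81 CPM), which binds bacterial lipopolysaccharide, and AA467197 (−0.74, SE 0.09, 0.0406; 30.5 ± 1.80 against 51.0 ± 4.87 CPM), known as NMES1, a small mitochondrial protein. Both were named after the values were seen. With pairs edgeR passed 275 (83 higher, 192 lower), of which 95 changed at least 2-fold (21 higher, 74 lower).

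With pairs in the knockout, Il22 rose (4.48, SE 0.52, adjusted p = 0.00647), as did Il12rb2 (1.5, SE 0.20, 0.0114), Dennd5a (0.99, SE 0.07, 0.00130), Cd40lg (0.94, SE 0.11, 0.00576) and Itpr1 (0.47, SE 0.09, 0.0478). Il17f fell (−0.68, SE 0.13, 0.0402), while Il17a (−0.22, SE 0.23, 0.767), Csf2 (0.16, SE 0.28, 0.872) and Il2 (−0.21, SE 0.14, 0.622) did not pass. Orai1 was at 1.01 (SE 0.35, 0.264), from levels under 1 CPM. Maf (−1.30, SE 0.10, 0.00146), Il1rn (−0.86, SE 0.13, 0.0148) and Il9 (−0.57, SE 0.09, 0.0190) are 3 of the 4 non-pathogenic signature genes that fell, of 8 (7 adjusted over the list alone; camera adjusted p = 1.19e-09 with and 1.58e-05 without pairs; adjusted p = 0.132 and 0.470 with an estimated correlation). Ldlrad4 (−1.15, SE 0.10, 0.00306) and Id1 (−0.90, SE 0.10, 0.00511) are among 4 of 15 TGF-β response genes that fell, where 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 1.75e-08 with and 1.02e-04 without pairs; adjusted p = 0.132 and 0.470 with an estimated correlation). In the pathogenic signature 2 of 14 rose, 5 adjusted over the list alone (camera adjusted p = 0.00586 with and 0.0274 without pairs; adjusted p = 0.184 and 0.470 with an estimated correlation). Of 20 Th17 lineage genes 1 rose and 3 fell, Ccl20 (−1.46, SE 0.18, 0.00682) among them (2 higher and 10 lower adjusted over the list alone; camera adjusted p = 2.17e-07 with and 3.95e-04 without pairs; adjusted p = 0.144 and 0.470 with an estimated correlation). Glycolysis genes were higher (2 of 22 rose, 8 adjusted over the list alone; camera adjusted p = 1.19e-09 with and 0.0213 without pairs; adjusted p = 0.276 and 0.731 with an estimated correlation). Of 11 B cell markers 2 rose, also 2 adjusted over the list alone (camera adjusted p = 0.00229 with and 0.0804 without pairs; adjusted p = 0.160 and 0.731 with an estimated correlation).

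Neither gene that passed without pairs in the knockout stayed past the test in every fit with 1 library left out (highest adjusted p = 0.265 for Lbp and AA467197), and a fit on the 6 knockout libraries alone passed 0 genes, while DESeq2 passed 148. The paired count of 275 was 11, 27 and 119 without knockout pair 1, 2 or 3 and 490 without wild-type pair 2. The full naming rule would take 39 genes past this paired test, not all of them named here. Of these, 4 stayed past the test in every case, Maf and Dennd5a among them. Lists past camera without pairs numbered 9 (3 without knockout npTh17 library 1, 5 without knockout pTh17 library 2), none with an estimated correlation.

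Of genes past the paired test, 19 were higher in pTh17 in both genotypes and 61 were lower in both, with 0 in opposite directions. Over all genes the culture differences of knockout and wild type correlated at 0.329 without pairs.

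The interaction asks whether the knockout effect differs between pTh17 and npTh17. For Il17a it was −0.12 (SE 0.45), for Il17f −0.52 (SE 0.47), for Il2 −0.46 (SE 0.40), for Csf2 0.23 (SE 0.59), for Il22 1.22 (SE 1.15) and for Orai1 1.13 (SE 0.41), each with adjusted p = 0.999. edgeR passed 0 of 15238 genes (548 at unadjusted p < 0.05), limma voom and DESeq2 passed 0, and with pairs 0 passed (882 at unadjusted p < 0.05, smallest adjusted p = 0.789). No difference in the knockout effect between the cultures was found for any gene, and interactions of 1.5-fold were recovered in 2.99% of simulated genes. Of the lists, oxidative phosphorylation was the 1 past camera (75 genes, 24 higher and 51 lower, median −0.05, adjusted p = 0.0491; adjusted p = 0.931 with an estimated correlation).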

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

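The tests by splits were set down before their values were seen, but those with libraries paired were added after the paired counts were known. For knockout against wild type and for the cultures they take all 10 ways to divide the 6 libraries into 3 and 3, and for the interaction 50 drawn splits that relabel the genotypes within each culture. With pairs they exchange the cultures within pairs, in 4 ways per genotype and 32 for the interaction. Each counts how many splits, the real one included, give a count as large as the real one.

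The oxidative phosphorylation list differed in its knockout effect between the cultures, with a median interaction of −0.0542 over 75 genes (51 lower, 24 higher) and no single gene past the test. Camera passed it with the preset correlation at adjusted p = 0.0491, and not with an estimated correlation (adjusted p = 0.931). All 50 of 50 splits had at least the real count of 1 list past camera for the interaction, and the highest had 20. With libraries paired, 28 of 32 splits had at least the real 1 list, and the highest other had 12; nearly any split reaches a count of 1, and mixed splits carry the knockout or culture effect, so these counts do not test this list. In npTh17 the list was higher in the knockout (median 0.08, camera adjusted p = 0.00137, and 0.649 with an estimated correlation). In pTh17 the median was 0.02 (camera adjusted p = 0.765). A change in mitochondrial gene expression in knockout npTh17 cells could also lie behind the interaction, and neither the splits nor the mRNA levels here test that apart.

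For the interaction counts of genes, the real count was 0, so all 50 of 50 splits reach it for genes past the test and for genes at least 2-fold changed (highest other 480 and 284). With pairs all 32 of 32 splits reach it (highest other 540 and 319). A count of 0 is reached by any split, so these values say nothing about the interaction.

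For knockout against wild type there are too few splits (10) to give a small p. In npTh17, 1 of 10 splits reached the real 121 genes (highest other 0) and 1 of 10 the real 55 genes at least 2-fold changed (highest other 0). For lists past camera 3 of 10 reached the real 12 (highest other 14). In pTh17, 1 of 10 reached 72 genes (highest other 2), 1 of 10 reached 41 (highest other 2), and 1 of 10 reached 13 lists (highest other 10).

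For pTh17 against npTh17 without pairs there are also 10 splits. In wild type all 10 of 10 reach the real 0 genes and the real 0 genes at least 2-fold changed, and 3 of 10 reach the real 4 lists (highest other 12). In knockout 1 of 10 reaches 2 genes (highest other 0), 1 of 10 reaches 1 gene at least 2-fold changed (highest other 0), and 3 of 10 reach 9 lists (highest other 15). A split that mixes the groups and still passes 10 to 15 lists points to structure among the libraries that camera with the preset correlation counts as change, so those list counts say little without the estimated correlation.

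With pairs there are 4 splits per genotype, too few to give a small p. In wild type 1 of 4 reached 89 genes (highest other 0), 1 of 4 reached 28 (highest other 0) and 1 of 4 reached 9 lists (highest other 5). In knockout 1 of 4 reached 275 genes (highest other 0), 1 of 4 reached 95 (highest other 0) and 1 of 4 reached 12 lists (highest other 5).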

How the results depend on the processing

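Tests with libraries paired by genotype and number, with a random block, with the hypoxia score, without the genes within 10 Mb of Orai1 and with a library left out of a list count or correlation were chosen after the result was seen; the other settings were fixed before. The hypoxia score is the mean of 16 hypoxia-induced genes per library. Leaving out a library or a pair also lowers the power of the test, so a smaller count need not rest on that library.

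Knockout against wild type in npTh17 (121 genes, 55 at least 2-fold): DESeq2 gave 393 and 108, no filter on low counts 235 and 110, the replicate block 253 and 94, the hypoxia score as a covariate 376 and 116, and glmTreat against 1.5-fold 16. Leaving out each library gave 35 to 124 and 21 to 62.

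In pTh17 (72 and 41): DESeq2 gave 269 and 89, no filter 177 and 94, the replicate block 181 and 70, the hypoxia score 267 and 90, the fit on the groups compared only 8 and 8, and glmTreat 12. Leaving out each library gave 28 to 75 and 17 to 43. Every other setting in either culture stayed within 1.5 times of the counts, and every setting kept the direction of each named gene that passed.

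pTh17 against npTh17 in wild type (0 and 0): DESeq2 gave 16 and 5, no filter 11 and 6, the replicate block 5 and 3, the replicate block within genotype 89 and 28, limma voom with that block 88 and 27, and the hypoxia score 51 and 17. Leaving out each pair of libraries from the blocked fit gave 0 to 78 and 0 to 33.

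In knockout (2 and 1): DESeq2 gave 148 and 54, no filter 111 and 54, the replicate block 89 and 40, the groups compared only 0 and 0, the replicate block within genotype 275 and 95, limma voom with a random block 90 and 35, limma voom with the block within genotype 269 and 93, the hypoxia score 167 and 60, limma trend on the authors' CPM plus 1 gave 2 at least 2-fold changed, and glmTreat 0. Leaving out each library gave 0 to 3 and 0 to 1, and leaving out each pair from the blocked fit gave 11 to 490 and 9 to 126. The interaction gave 0 genes in every setting.

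Lists past camera in npTh17 (12) were 2 with an estimated correlation, and in pTh17 (13) were 5 with it and 7 by fry. For pTh17 against npTh17 in wild type (4) they were 0 with an estimated correlation, 0 by fry, 8 with the replicate block, 9 with the block within genotype, and 3 to 12 with each library left out. In knockout (9) they were 0 with an estimated correlation, 0 by fry and 3 to 12 with each library left out. For the interaction (1) they were 0, 0 and 0 to 2.

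The correlation of knockout effects between the cultures (0.512) was 0.588 with a filter at 1 CPM, 0.976 over genes past the test in either, and 0.413 to 0.482 with each library left out. That of the culture differences between the genotypes (0.329) was 0.426 with the filter and 0.222 to 0.360 with each library left out. The gene filter was applied anew in each left-out fit. The genes therefore differ, and these ranges do not show the weight of single libraries alone.

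Signs turned only for always-named genes that did not pass the test. Ranges with each library left out, knockout against wild type in pTh17: Stim1 −0.045 to 0.014 and Stim2 −0.076 to 0.0081. pTh17 against npTh17 in wild type: Orai1 −0.28 to 0.048, Orai3 −0.10 to 0.46, Stim2 −0.030 to 0.033, Il17a −0.38 to 0.088, Il17f −0.32 to 0.018 and Csf2 −0.41 to 0.35. In knockout: Orai2 −0.18 to 0.0087, Stim1 −0.049 to 0.036, Stim2 −0.059 to 0.025, Il17a −0.47 to 0.10, Csf2 −0.025 to 0.32 and Il2 −0.50 to 0.033. Csf2 in wild type (−0.058) was 0.040 by limma voom, 0.061 by limma trend on the CPM as deposited and 0.044 with the random block. Stim1 in knockout (−3.8e-06) was 0.00157 by limma voom, 3.9e-04 with the replicate block, 0.00138 with the block within genotype, 0.00165 with the random block, 0.00186 by limma voom with the block within genotype and 0.00563 with the hypoxia score.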

Other observations

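All but 1 of the tests in this part were chosen after the result was seen; the exception is that of carried-over B cells. Genes induced by low oxygen differed more between the libraries of a group than between the group means. The mean log2 CPM of 16 such genes was 5.06, 6.56 and 6.09 in wild-type npTh17 libraries 1 to 3 and 5.26, 6.77 and 6.34 in wild-type pTh17, against 5.70, 6.49 and 5.35 in knockout npTh17 and 6.08, 6.60 and 5.41 in knockout pTh17. The order of the numbers was the same in both cultures of a genotype, and in all 6 pairs of libraries with the same genotype and number the value was higher in pTh17. The group means of wild type and knockout were 5.90 and 5.84 in npTh17 and 6.12 and 6.03 in pTh17.

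Some genes were all but absent in wild type and present in the knockout; they were chosen after the values were seen. Epha2, an ephrin receptor, was at 0.615 ± 0.180 CPM in wild-type and 5.55 ± 1.20 CPM in knockout npTh17 (log2 fold change 3.16, adjusted p = 0.00212, edgeR) and at 0.771 ± 0.383 and 3.95 ± 1.31 CPM in pTh17 (2.37, 0.0132). The non-coding RNA Gm38326 had no counts in any wild-type library and was at 0.881 ± 0.0763 CPM in knockout npTh17 and 0.941 ± 0.146 CPM in knockout pTh17. Gh, which encodes growth hormone, passed in both cultures with log2 fold changes of 7.73 in npTh17 and 7.32 in pTh17. As the Cre status of the controls is not given, the Orai1 deletion and the Cre transgene cannot be told apart as its source.

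Some genes are on in 1 library and off in another of the same group, and follow the library number within a genotype. If the numbers arose only at library preparation from 1 pool, about 1 in 3 such genes would share their highest number across cultures. All 14 of the 14 genes chosen in wild-type npTh17 do (19 of 21 chosen in wild-type pTh17, 3 of 4 in knockout npTh17 and 13 of 15 in knockout pTh17). This argues against library preparation from 1 pool alone. It does not exclude it, as such genes can move together, and preparing libraries of 1 number together was not tested apart. If separate animals stood behind the numbers, the order by number would give the highest correlation between cultures of the 6 possible orders, and it does in both genotypes and from both cultures, with a lowest value of 0.879. Portions of 1 pool kept apart from before the culture could carry differences of culture state, but the pseudogene Gm13394 is 115 times as high in the highest as in the lowest wild-type npTh17 library, and that cannot tell this from animals of different origin. Genotyping the mice, or reads over strain variants in each library, would tell them apart.

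Il17a and Il17f fell in the knockout. If fewer cells had been stimulated, activation markers would fall as the cytokines did. Their medians were −0.13 (npTh17) and −0.17 (pTh17), far smaller falls than those of the cytokines. How far these markers drop with fewer stimulated cells at 48 h was not tested, and Lag3 among them fell. Il2, Egr3, Cd40lg and Nfatc1, which are not in that list, fell too, so fewer stimulated cells are not excluded. Loss of calcium entry upstream of NFAT may lower these cytokines per cell, as the lower NFAT target list would have it, and this stays open without a rescue. Nuclear NFAT and IL-17A staining per cell, with and without ionomycin, would separate it from a change in cell makeup.

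Many genes changed in the knockout in both cultures. If variants in a segment around Orai1 caused this by acting on nearby genes, most changed genes would lie within 10 Mb of Orai1. With Orai1 itself left out, 3.33% of the changed genes in npTh17 (4 of 120) and 1.41% in pTh17 (1 of 71) do. Of the tested genes 1.32% do (Fisher exact test p = 0.0744 and 0.611). This argues against variants that act only on nearby genes as the whole cause. A variant near Orai1 that changes distant genes would not be seen this way and is not excluded. B cells and antigen-presenting cells carried over in knockout 2 and 3 were considered next. If they caused the shared changes, knockout 1 would lack these, as its B cell markers are at or below wild type. Its median gene of the 58 shared ones other than Orai1 keeps 0.960 (npTh17) and 0.989 (pTh17) of the change seen in knockout 2 and 3. Those genes passed a test that included knockout 1, which favours genes changed in all 3 libraries. The values show that they changed in knockout 1 too, and cannot tell whether carried-over cells changed other genes. The genotype at Orai1 itself could explain the shared changes, and other differences between the pools of mice, such as the Cre transgene or litter, were not tested. Knockouts and Cre-carrying controls from the same litters, kept as separate animals, would separate these.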
